A study of Mus with 18 samples.

How the data were processed

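RNA of RAW264.7 cells was sequenced in 18 libraries, 3 for each of 6 groups, and the labels give each library's treatment and the replicate number in its title. The deposited count table holds whole-number reads or fragments per gene symbol, with no normalization, per the values of the table. The deposited FPKM table holds fragment counts scaled to gene length and library total, made by the authors, per its title and values. The genome build GRCm39 and the tool CASAVA are named per the submitters' processing notes. The aligner, the counting tool, the annotation and any strand setting are not given in the sources used here.

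The count table holds 35510 genes and the table of FPKM has 22384. At least 1 count was found for 22370 genes. Every column of both tables was matched to 1 sample by its title, and 0 columns belong to no sample. Gene symbols were used as the tables give them, and 32470 were found in a RefSeq table of the assembly GRCm38, which was used for names and for which genes are neighbours, not for coordinates. Replicates were checked for duplicates by a chi-square statistic of their counts. Per degree of freedom it was 13.1 to 83.4 in pairs within LPS and POx-SA and 2.63 to 14.2 within other groups. All 18 exceeded sampling noise. Pearson correlations of log2 CPM within these pairs, across genes, were 0.966 to 0.992.

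Total counts were 9755591 to 19759549 per library, and 99.9% of them fell in tested genes in each group. Mitochondrially encoded genes took 2.90% to 7.17% of counts. At these depths a gene with 3 counts or fewer in a group was treated as near the floor. Against a group at 0, a fold was computed against a floor of 3 counts over the group and given as a lower bound. With 1 to 3 counts the ratio was given with an exact 95% counting interval.

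The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on counts. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13482. Libraries were scaled by TMM factors (0.812 to 1.15), and all 18 entered 1 fit with a term per group. The 6 groups, though unequal in spread, shared its estimate (12 residual degrees of freedom, common dispersion 0.0219). P-values were adjusted by the Benjamini-Hochberg method within each of 13 comparisons, and a gene was called at an adjusted p below 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM are counts scaled to the TMM-adjusted library size, and SD is over 3 libraries.

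Gene lists numbered 31 and held 729 genes, of which 724 were matched, and 22 stood in more than 1 list. Mitochondrially encoded genes were matched by the symbols without prefix that the tables use. A list with at least 3 tested members was tested by camera (limma 3.58.1) with a preset correlation of 0.01, and again with a correlation estimated per list. Rotation tests by fry, which ask whether a list's genes move on balance in 1 direction without comparing them with other genes, were a further alternative.

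The lists, the comparisons, the main test, most alternatives and the rule for named genes were chosen before the data were examined. The rule names, for LPS against untreated and each polymer against LPS, the 8 genes with the largest and the 8 with the smallest log2 fold change, and 5 each in the other comparisons. Each had an adjusted p below 0.05, 3 values that do not overlap the other 3, at least 5 CPM in the higher group and no predicted or clone name. It adds a panel of 22 genes and, from each list described, up to 4 called members with the smallest p, or the 2 with the highest expression where none was called. The genes Gm42427 and ND3 and the Y-linked genes were named after their values were seen. Some genes that the rule names are not reported here.

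The script of the tests was tested on simulated data drawn from the means and library sizes of these samples, with 200 of 13482 genes changed. In LPS against untreated and in POx-SA, PPLG-SA, PPLG-2V-SA and PPLG-4V-SA against LPS, it recovered 37.3%, 35.8%, 47.8%, 22.4% and 35.8% of genes changed 1.5-fold. It recovered 74.6%, 71.6%, 58.2%, 65.7% and 61.2% of those changed 2-fold, and 90.9%, 93.9%, 89.4%, 89.4% and 95.5% of those changed 4-fold. False calls numbered 2, 5, 9, 8 and 5. The changed list was called in each of the 5 comparisons, and of the other lists 1 was called in LPS against untreated and 0 in the others.

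Whether replicate numbers pair libraries was checked from the correlation, across genes, of deviations from group means. Of 45 pairs with the same number, 8 had a correlation above 0.1, and 7 of 18 libraries correlated best with a library of their own number. For LPS and LPS + POx-SA all 3 pairs lay above 0.1, so by this rule, from the data and not from the labels, their numbers pair the libraries. The replicate block was an alternative in every comparison.

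Alternatives were the size factors of DESeq2 in edgeR, the test of DESeq2 1.42.0, no filter on low counts, a filter of at least 1 CPM in 3 libraries, limma-trend on log2 of FPKM plus 1 or plus 0.1, a call that also needs a 2-fold change, only the 2 compared groups in the fit, the replicate block, and leaving out each library in turn. Added after the data were seen were replicates 3 of LPS and LPS + POx-SA both left out, removal of each library's gene-length trend, and the replicate block with only the LPS and LPS + POx-SA groups in the fit. Lengths for this trend were those implied by counts and FPKM, found for 100% of tested genes.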

Results

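RNA was sequenced from RAW264.7 cells, a mouse macrophage-like line, in 6 groups of 3 libraries each. LPS, a component of the outer membrane of Gram-negative bacteria, activates macrophages through the receptor TLR4. According to the labels, 1 group was left without treatment, 1 was stimulated by LPS, and 4 were treated, after LPS, by what the series design calls sialic polymers. These are labelled POx-SA, PPLG-SA, PPLG-2V-SA and PPLG-4V-SA. The labels give no doses, times or meaning of these codes, so doses and times cannot be compared between groups. Siglecs, the receptors named in the series title, are lectins of immune cells that bind sialic acids.

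Total counts per library were 9755591, 10546678 and 10992859 without treatment, and 15886080, 14761261 and 15971157 with LPS. They were 13417940, 14749446 and 16033361 with LPS + POx-SA, and 13479878, 14426938 and 15543642 with LPS + PPLG-SA. They were 15688248, 15639379 and 19759549 with LPS + PPLG-2V-SA, and 16208465, 16720984 and 17385958 with LPS + PPLG-4V-SA. Values below are counts scaled to library size (CPM) as mean ± SD (n = 3) and log2 fold changes ± SE. Genes said to rise or fall had an adjusted p below 0.05 by edgeR among 13482 tested genes. For gene lists the median is that of the members' log2 fold changes and the adjusted p that of camera over the 30 lists tested. List counts adjusted over the list alone were equal to those over all genes unless both are given. Of 454 named values in the text, each of a gene in a comparison, 435 were called. The labels do not say whether replicates are separate cultures, so each p measures only the spread between these samples, and counting intervals and bounds cover counting error only. Counting of shared reads is not given, so values of ND4L and genes with close copies, like Hspa1a, Hspa1b, histones and Stfa genes, are uncertain.

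**Figure D1:**
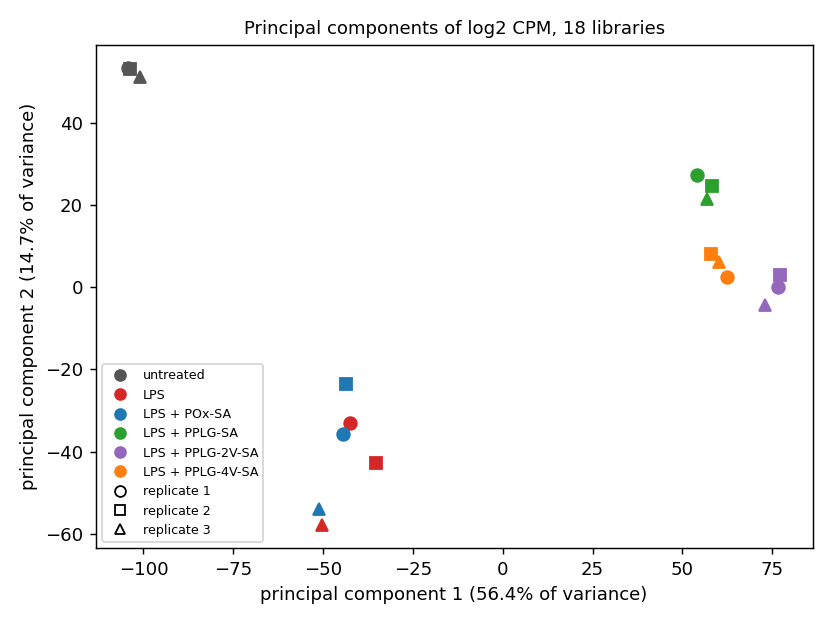
Each point is 1 of the 18 libraries on the first 2 principal components of log2 CPM, which hold 56.4% and 14.7% of the variance. Untreated libraries lie at one side, the 9 libraries of the PPLG groups at the other, and replicate 3 of LPS beside replicate 3 of LPS + POx-SA.

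The first comparison asked what LPS changed. Interferon-stimulated genes were higher after LPS, and transcripts of replication-dependent histones were lower. Tnf, the cytokine tumour necrosis factor, rose from 323 ± 11.4 to 839 ± 138 CPM (log2 fold change 1.38 ± 0.12, adjusted p = 3.27e-08). Il10, an anti-inflammatory cytokine, rose from 13.1 ± 0.191 to 142 ± 37.2 CPM (log2 fold change 3.44 ± 0.20, adjusted p = 6.83e-10). Nos2, the inducible nitric oxide synthase, was already at 2489 ± 96.6 CPM without LPS and fell to 1254 ± 102 CPM (log2 fold change -0.99 ± 0.14, adjusted p = 1.23e-05). In total 4149 genes were higher and 3833 lower after LPS. On deposited FPKM plus 1 the split was 5927 and 2304, with a median over all genes moved by 0.20, so directions are relative to the count scaling.

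Interferon-stimulated genes had 39 of 44 rose, 0 fell and 5 were not called (41 and 0 adjusted over the list alone; median 1.71, or 1.66 with genes at 0 at their bound; adjusted p = 5.82e-17). Rsad2, an antiviral enzyme, rose by 2.19 ± 0.10, Oasl1 by 2.57 ± 0.13, Irf9, a subunit of the interferon-activated transcription factor complex, by 2.09 ± 0.13, and Usp18 by 1.80 ± 0.11. Isg15 rose by 2.24 ± 0.22, Ifit1 by 1.73 ± 0.23 and the chemokine gene Cxcl10 by 2.51 ± 0.25. Of the S phase genes, 28 of 32 rose, 0 fell and 4 were not called (28 and 1 adjusted over the list alone; median 1.26; adjusted p = 8.15e-13, adjusted p = 0.222 with an estimated correlation). Mcm10 rose by 3.37 ± 0.15. Of the G2 and M phase genes, 30 of 32 rose, 1 fell and 1 were not called (31 and 1 adjusted over the list alone; median 1.67; adjusted p = 6.46e-20, adjusted p = 0.0540 with an estimated correlation), with Kif2c at 3.31 ± 0.16 and Plk1, a mitotic kinase, at 2.28 ± 0.14. Of the replication-dependent histones, 0 of 20 rose, 19 fell and 1 were not called (median -3.52; adjusted p = 7.24e-12), with H2bc4 at -3.87 ± 0.25 and H4c9 at -4.06 ± 0.28. Of the unfolded protein and integrated stress response, 20 of 29 rose, 3 fell and 6 were not called (median 0.84; adjusted p = 1.03e-06, adjusted p = 0.294 with an estimated correlation), with the transcription factor gene Xbp1 at 2.73 ± 0.10 and Herpud1 at 2.71 ± 0.10.

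Lysosome and phagocytosis genes fell more often than they rose: 6 of 36 rose, 17 fell and 13 were not called (6 and 18 adjusted over the list alone; median -0.33; adjusted p = 0.0273, adjusted p = 0.775 with an estimated correlation). Psap fell to a log2 fold change of -1.82 ± 0.15, while the Fc receptor gene Fcgr1 rose by 1.93 ± 0.18. Of the osteoclast differentiation genes, 2 of 15 rose and 8 fell (adjusted p = 0.0489, adjusted p = 0.144 with an estimated correlation). The inflammatory cytokines were mixed: 10 of 21 rose, 5 fell and 6 were not called (median 0.57; adjusted p = 0.604). Csf1, a macrophage growth factor, rose by 2.76 ± 0.25, Il27 by 1.78 ± 0.19 and Il6 by 1.57 ± 0.25, while Ebi3 changed by -0.88 ± 0.09. Of the chemokines, 4 of 13 rose and 4 fell (adjusted p = 0.955), with Ccl4 at 1.27 ± 0.12, Ccl5 at 0.62 ± 0.15 and Cxcl2, a neutrophil attractant, at -1.53 ± 0.12. Of the negative regulators of TLR signalling, 11 of 26 rose and 6 fell (adjusted p = 0.184), with Socs3, an inhibitor of cytokine signalling, at 1.27 ± 0.10. Of the Siglec receptors and phosphatases, 3 of 10 rose and 4 fell (adjusted p = 0.755). Siglec1 rose by 1.65 ± 0.14 and Ptpn6, which encodes the phosphatase SHP-1, by 1.06 ± 0.12, while Cd33 changed by -1.33 ± 0.17. In the panel of 22 genes 11 rose, 5 fell and 6 were not called. Ptgs2, the inducible cyclooxygenase, rose by 0.69 ± 0.23, though LPS replicate 3 (4320 CPM) lay below the untreated 4364 to 4752 CPM and 2 alternatives did not call it, while Nfkbia changed by -0.65 ± 0.11, Arg1 by -2.73 ± 0.51 and Mrc1 by -2.56 ± 0.66.

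The largest rises were those of Steap4 at 4.74 ± 0.60, Tnfaip6 at 4.49 ± 0.43, Trib1 at 4.28 ± 0.43 and the mitotic genes Nusap1 at 4.00 ± 0.20, Hmmr at 3.84 ± 0.25, Sapcd2 at 3.83 ± 0.33, Ndc80 at 3.76 ± 0.13 and Cenpf at 3.71 ± 0.34. The largest falls were those of the histone genes H2ac6, 194-fold (counting interval 53.1 to 1615) lower, H2bc8 at -6.01 ± 0.35, H2bc23 at -5.56 ± 0.25, H2bc6 at -5.49 ± 0.35 and H3c6 at -5.30 ± 0.38, with the chaperone gene Hspa1b at -6.55 ± 0.47, Ovgp1 at -6.44 ± 0.68 and Chil6 at -5.14 ± 0.55.

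Camera called 7 of the 30 lists, 2 of them with an estimated correlation too. Among the others, NF-kB pathway and feedback genes had 10 of 28 rose and 9 fell (adjusted p = 0.604), TLR4 signalling components 11 of 30 rose and 5 fell (adjusted p = 0.184) and inflammasome genes 7 of 21 rose and 6 fell (adjusted p = 0.955). Classical activation effectors had 10 of 30 rose and 9 fell (adjusted p = 0.955) and MHC class I genes 7 of 21 rose and 3 fell (adjusted p = 0.439). MHC class II genes had 1 of 9 rose and 4 fell (adjusted p = 0.604), and mitochondrially encoded genes 2 of 13 rose and 7 fell (adjusted p = 0.133). Nuclear oxidative phosphorylation genes had 11 of 36 rose and 8 fell (adjusted p = 0.955), which became 10 and 15 without replicates 3 of LPS and LPS + POx-SA. The balance of 6 lists turned on FPKM plus 1. Sialic acid metabolism had 8 of 25 rose and 9 fell (adjusted p = 0.715), against 11 and 4 there, and alternative activation markers 5 of 17 rose and 8 fell (adjusted p = 0.401), against 6 and 5. Glycolysis and hypoxia genes had 3 of 29 rose and 14 fell (adjusted p = 0.184), against 12 and 7, and cholesterol biosynthesis 5 of 23 rose and 6 fell (adjusted p = 0.955), against 15 and 3. LXR targets had 2 of 12 rose and 4 fell (adjusted p = 0.716), against 4 and 3, and NRF2 targets 6 of 21 rose and 7 fell (adjusted p = 0.715), against 9 and 5. Among cell type lists, macrophage identity genes had 4 of 23 rose and 13 fell (4 and 14 adjusted over the list alone; adjusted p = 0.328), dendritic cell markers 3 of 8 rose and 0 fell (adjusted p = 0.604), lymphocyte markers 0 of 3 rose and 0 fell (adjusted p = 0.955), neutrophil and mast cell markers 1 of 3 rose and 2 fell (adjusted p = 0.184) and fibroblast markers 0 of 5 rose and 3 fell (adjusted p = 0.107). On plain totals the neutrophil and mast cell markers summed to 2041 ± 105 CPM untreated and 201 ± 43.5 CPM with LPS. Of the epithelial and endothelial markers only Pecam1 and Vwf were tested, too few for a list test, and Vwf stood at -0.89 ± 0.34, a call lost under 9 alternatives. Median and mean differed in sign for Siglec receptors (0.07 and -0.05), inflammasome genes (-0.08 and 0.09), MHC class II (-0.26 and 0.33), mitochondrially encoded genes (-0.57 and 0.94) and NRF2 targets (0.01 and -0.18), and the camera direction was down for each and for cholesterol biosynthesis, whose median of 0.02 lay above 0.

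**Figure D2:**
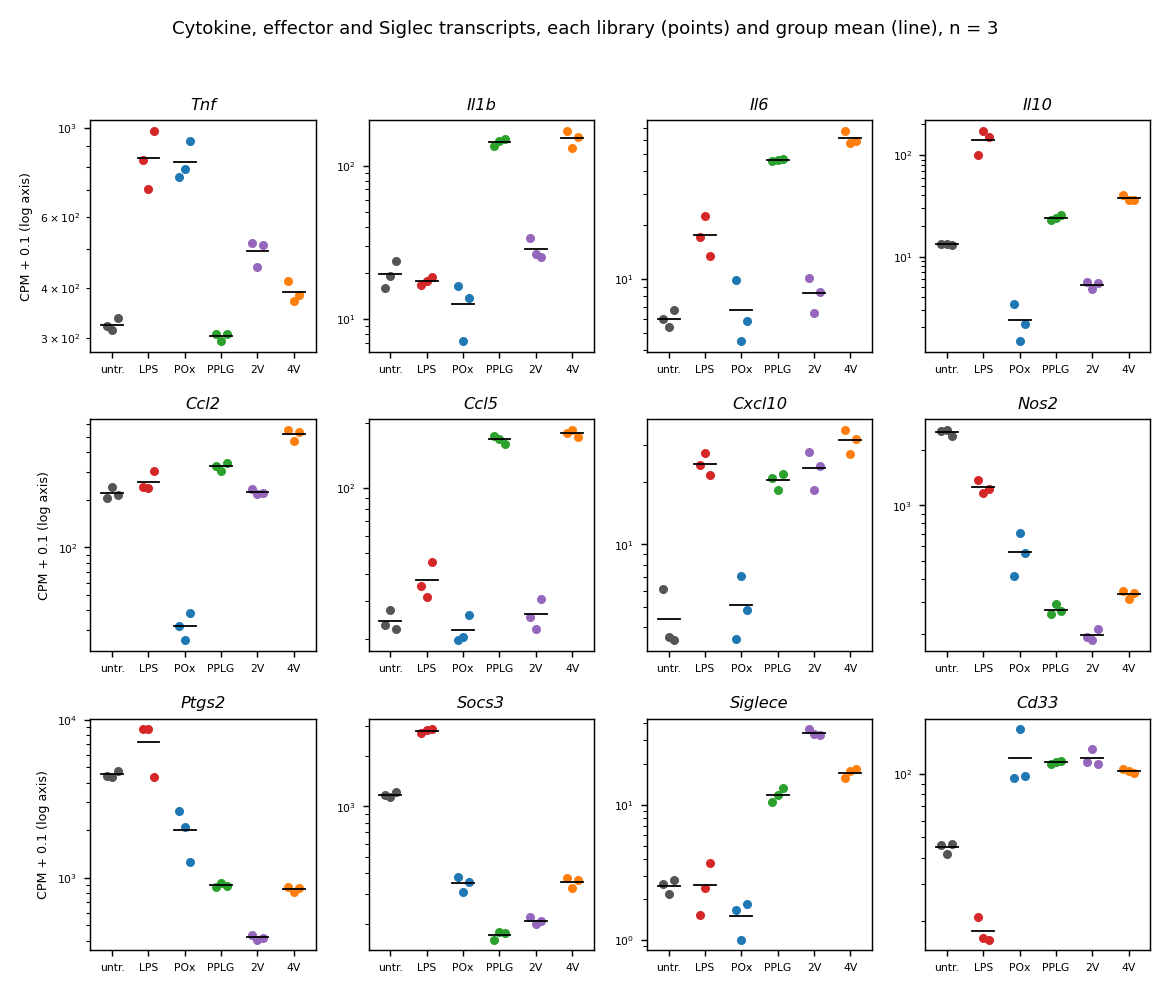
Points are CPM plus 0.1 of single libraries on a log axis for 12 panel genes in the 6 groups, and lines are group means (n = 3). Il6, Il1b and Ccl5 stood higher with PPLG-SA and PPLG-4V-SA than in the other groups, and Il10, Nos2, Ptgs2 and Socs3 stood below LPS with each polymer.

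The comparison of LPS + POx-SA with LPS asked what POx-SA, given after LPS, changed. Interferon-stimulated genes, cytokines and negative regulators were lower with POx-SA than with LPS, and NRF2 targets were higher. Il10 fell from 142 ± 37.2 to 2.25 ± 1.01 CPM (log2 fold change -5.97 ± 0.24, adjusted p = 1.43e-11). Ccl2, a monocyte attractant, fell from 261 ± 38.7 to 31.9 ± 6.22 CPM (log2 fold change -3.03 ± 0.14, adjusted p = 5.62e-11). Tnf did not differ, at 839 ± 138 CPM with LPS and 823 ± 92.4 CPM with POx-SA (log2 fold change -0.03 ± 0.11, 95% interval -0.27 to 0.21). In total 2992 genes were higher and 3247 lower. On FPKM plus 1 the split was 2232 and 3934.

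Of the interferon-stimulated genes, 0 of 44 rose, 39 fell and 5 were not called (0 and 40 adjusted over the list alone; median -1.50, or -1.47 with genes at 0 at their bound; adjusted p = 2.05e-31). Usp18 changed by -2.85 ± 0.12, Oas2 by -2.34 ± 0.11, Xaf1 by -2.97 ± 0.13, Isg15 by -1.52 ± 0.21, Ifit1 by -1.40 ± 0.21 and Cxcl10 by -2.27 ± 0.23. Of the inflammatory cytokines, 3 of 21 rose, 13 fell and 5 were not called (3 and 14 adjusted over the list alone; median -0.98; adjusted p = 3.66e-07). Il33 changed by -4.80 ± 0.20, Csf2 by -3.92 ± 0.26, Il27 by -2.32 ± 0.19 and Il6 by -1.41 ± 0.23. Of the chemokines, 1 of 13 rose, 6 fell and 6 were not called (1 and 8 adjusted over the list alone; median -0.76; adjusted p = 2.96e-04, adjusted p = 0.190 with an estimated correlation), with Ccl7 at -2.95 ± 0.21 and Ccl5 at -0.76 ± 0.14. Of the negative regulators of TLR signalling, 3 of 26 rose, 15 fell and 8 were not called (median -0.68; adjusted p = 1.37e-10), with Socs3 at -3.02 ± 0.10 and Il1rn, the antagonist of the interleukin-1 receptor, at -2.11 ± 0.12. Of the classical activation effectors, 2 of 30 rose, 20 fell and 8 were not called (2 and 21 adjusted over the list alone; median -1.17; adjusted p = 2.13e-11). Saa3 changed by -4.02 ± 0.15, the complement gene C3 by -2.76 ± 0.16, Nos2 by -1.16 ± 0.14 and Ptgs2 by -1.85 ± 0.24. Nfkbia, the inhibitor of NF-kB, changed by -1.94 ± 0.11. Camera called 13 lists, 5 of them with an estimated correlation too.

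NRF2 targets, genes of the oxidative stress response, moved the other way: 15 of 21 rose, 1 fell and 5 were not called (16 and 1 adjusted over the list alone; median 1.03; adjusted p = 1.09e-10). Gclm rose by 2.35 ± 0.12, Prdx1 by 2.72 ± 0.18 and the haem oxygenase gene Hmox1 by 2.63 ± 0.21. Of the mitochondrially encoded genes, 10 of 13 rose, 0 fell and 3 were not called (median 1.06; adjusted p = 1.18e-05, adjusted p = 0.228 with an estimated correlation), with ND2 at 1.33 ± 0.15 and CYTB at 1.52 ± 0.18, and their share of counts was 3.07 ± 0.148% with LPS and 5.73 ± 1.25% with POx-SA. Of the S phase genes, 2 of 32 rose and 19 fell (3 and 19 adjusted over the list alone; adjusted p = 0.00201, adjusted p = 0.594 with an estimated correlation), with Mcm10 at -1.28 ± 0.12, and of the G2 and M phase genes, 2 of 32 rose and 19 fell (2 and 20 adjusted over the list alone; adjusted p = 4.67e-06, adjusted p = 0.272 with an estimated correlation), with Ccna2 at -1.79 ± 0.15. The Siglec and phosphatase list was not called, with 3 of 10 rose and 5 fell (3 and 6 adjusted over the list alone; adjusted p = 0.932). Its members went apart: Cd33 rose by 2.74 ± 0.17, while Siglec1 changed by -1.73 ± 0.14, Siglece by -0.79 ± 0.29 and Ptpn6 by -0.31 ± 0.12, calls that 7 and 8 of the alternatives did not make. For this list the median was -0.45, the mean -0.17 and the camera direction up. Among the 22 panel genes 2 rose, 14 fell and 6 were not called, the second riser being Ifnb1 at 1.99 ± 0.71, from raw counts of 3, 2 and 2 with LPS and 4, 3 and 19 with POx-SA. Without the last library it stood at 0.77, and 6 alternatives did not call it. On plain totals, neutrophil and mast cell markers, mostly the gene S100a8, summed to 54.3 CPM with POx-SA (201 with LPS, 2041 untreated). Fibroblast markers summed to 1788 CPM with LPS and 758 with POx-SA.

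The largest rises were those of the chaperone genes Hspa1a, 541-fold (counting interval 96.6 to 21404) higher, and Hspa1b at 7.37 ± 0.48, followed by the iron exporter gene Slc40a1 at 5.49 ± 0.28, Ptpn14 at 3.83 ± 0.20, Adcy3 at 3.26 ± 0.45, Clec4n at 3.26 ± 0.21, Chil6 at 3.05 ± 0.54 and Serpinb9b at 2.99 ± 0.39. The largest falls were those of Steap4, 392-fold (counting interval 70.0 to 15524) lower, Il10, Ccno at -5.15 ± 0.48, Csn1s1 at -5.05 ± 0.50, Gcnt2 at -5.02 ± 0.61, Il33, the iron-binding Lcn2 at -4.54 ± 0.14 and Marcks at -4.24 ± 0.19. Replicates 3 of LPS and of LPS + POx-SA deviated together (correlation 0.904 across 10055 genes). Fitting only these 6 libraries gave 1335 higher and 1726 lower, or 2601 and 2742 with the replicate block, though numbers pair only replicates 3.

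The comparison of LPS + PPLG-SA with LPS asked what PPLG-SA changed. Genes of cholesterol synthesis were higher and negative regulators of TLR signalling lower, and the cytokine genes parted. Il1b, which encodes interleukin-1 beta, rose from 17.6 ± 0.981 to 143 ± 7.70 CPM (log2 fold change 3.02 ± 0.21, adjusted p = 3.11e-09). Il6 rose from 17.6 ± 4.55 to 46.3 ± 0.406 CPM (log2 fold change 1.40 ± 0.21, adjusted p = 2.67e-05). Tnf fell from 839 ± 138 to 302 ± 7.15 CPM (log2 fold change -1.47 ± 0.12, adjusted p = 1.21e-08). Siglece, an inhibitory sialic acid receptor, rose from 2.45 ± 1.09 to 11.8 ± 1.49 CPM (log2 fold change 2.26 ± 0.23, adjusted p = 2.78e-07). In total 3939 genes were higher and 4133 lower, and on FPKM plus 1 these were 4395 and 3521.

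Cholesterol biosynthesis genes had 21 of 23 rose, 1 fell and 1 were not called (median 1.50; adjusted p = 3.34e-16). Insig1 rose by 3.58 ± 0.17 and Fdft1 by 2.38 ± 0.12. Interferon-stimulated genes had 25 of 44 rose, 10 fell and 9 were not called (median 0.60; adjusted p = 2.39e-04, adjusted p = 0.149 with an estimated correlation), with Gbp3 at 2.25 ± 0.15, Oasl2 at 2.13 ± 0.16 and Isg15 at -1.07 ± 0.21. Of the negative regulators, 4 of 26 rose, 18 fell and 4 were not called (median -1.33; adjusted p = 5.50e-11). Socs3 changed by -4.05 ± 0.11, Zfp36, which destabilises cytokine mRNAs, by -2.95 ± 0.12, Nfkbia by -2.10 ± 0.11 and Il10 by -2.56 ± 0.19. Of the chemokines, 3 of 13 rose, 7 fell and 3 were not called (median -0.98; adjusted p = 0.0127, adjusted p = 0.318 with an estimated correlation), with Cxcl2 at -3.98 ± 0.14, Ccl22, an attractant of T cells, at 4.91 ± 0.23, Ccl5 at 2.17 ± 0.14 and Ccl2 at 0.32 ± 0.13, a call that 6 alternatives did not make. Of the classical activation effectors, 7 of 30 rose, 21 fell and 2 were not called (median -1.19; adjusted p = 2.50e-04, adjusted p = 0.0772 with an estimated correlation). Saa3 changed by -3.62 ± 0.15, Nos2 by -2.21 ± 0.15, Ptgs2 by -3.02 ± 0.25 and the histidine decarboxylase gene Hdc by 5.62 ± 0.22. Of the inflammatory cytokines, 6 of 21 rose and 10 fell (adjusted p = 0.183), with Csf3 at -3.63 ± 0.17 and Csf2 at -3.99 ± 0.26.

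Of the G2 and M phase genes, 27 of 32 rose and 0 fell (adjusted p = 2.71e-10, adjusted p = 0.155 with an estimated correlation), with Kif20a at 1.98 ± 0.12. Of the S phase genes, 19 of 32 rose and 2 fell (adjusted p = 0.00548, adjusted p = 0.546 with an estimated correlation), with Tk1 at 1.98 ± 0.14. Of the glycolysis and hypoxia genes, 3 of 29 rose and 17 fell (adjusted p = 4.87e-06, adjusted p = 0.176 with an estimated correlation), with the glucose transporter gene Slc2a1 at -2.27 ± 0.12. Camera called 11 lists, 3 of them with an estimated correlation too. Of the Siglec and phosphatase genes, 7 of 10 rose and 3 fell (adjusted p = 0.103). Cd33 rose by 2.67 ± 0.17, Siglec1 by 0.63 ± 0.13 and Ptpn6 by 0.34 ± 0.12, the last not called under 4 alternatives. Sialic acid metabolism had 7 of 25 rose and 11 fell (adjusted p = 0.637), with the sialyltransferase gene St6gal1 612-fold (counting interval 109 to 24204) lower and the sialic acid lyase gene Npl at 2.46 ± 0.22. Of the 22 panel genes 8 rose, 9 fell and 5 were not called, among them Cd14, a co-receptor of LPS, at -1.31 ± 0.13, and Arg1, at least 5.38-fold lower.

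The largest rises were those of Atrnl1, 857-fold (counting interval 153 to 33898) higher, Baiap2l1 at 9.25 ± 0.21, the transcription factor gene Runx3, 615-fold (counting interval 110.0 to 24336) higher, Tnc at 6.36 ± 0.37, Serpinb6b at 6.31 ± 0.26, Tnik at 6.12 ± 0.47, Tnfsf15 at 5.96 ± 0.61 and Lin28b at 5.76 ± 0.26. The largest falls were those of S100a8, 8791-fold (counting interval 1577 to 347255) lower, Grhl2, at least 307-fold, Tex101, at least 227-fold, Spry2, at least 223-fold, Magohb, at least 202-fold, Rasgrf2, at least 187-fold, U90926, at least 177-fold, and Steap4, at least 148-fold. Of the neutrophil and mast cell markers, 0 of 3 rose, 3 fell and 0 were not called (median -7.96, or -4.98 with genes at 0 at their bound; adjusted p = 2.40e-06). In all, 63 genes stood at least 8-fold apart between the 9 libraries of the PPLG groups and the other 9 libraries, 14 higher and 49 lower. Summed CPM of 6 Y-linked genes was 306 to 395 in the libraries of the PPLG groups and 84.7 to 164 in the other 9, and this holds beside each gene group of the PPLG comparisons.

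**Figure D3:**
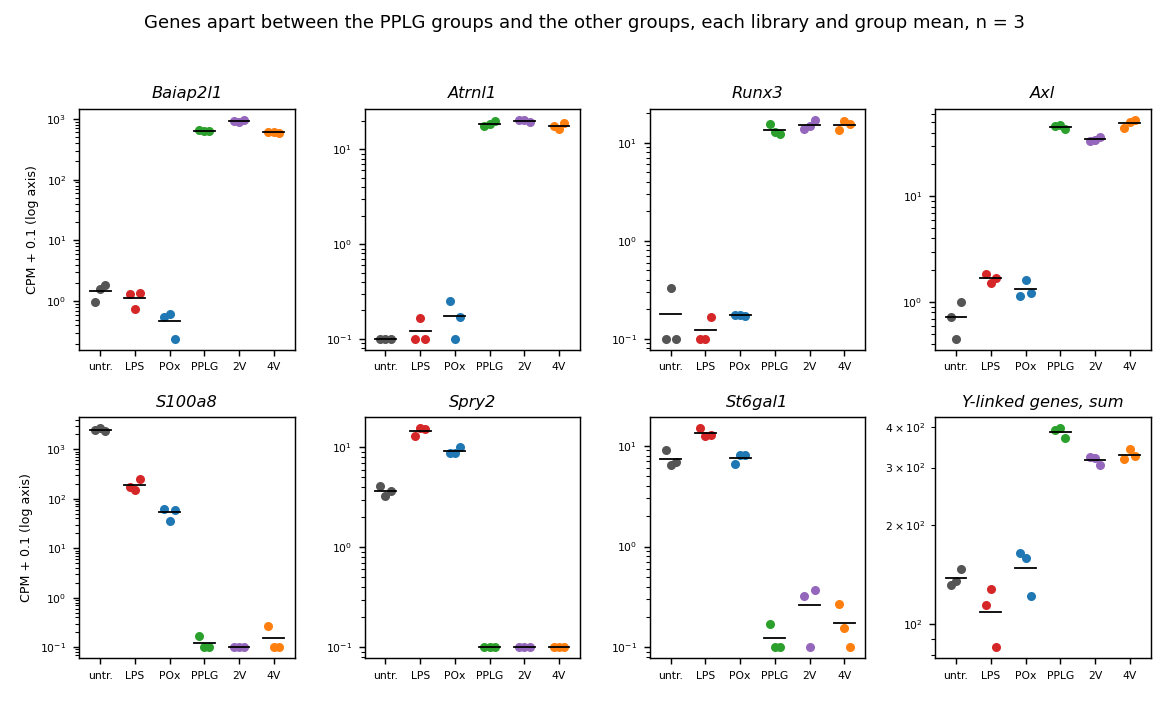
Points are CPM plus 0.1 of single libraries on a log axis for 7 genes and for the sum of 6 Y-linked genes in the 6 groups, and lines are group means (n = 3). In each panel the 9 libraries of the PPLG groups lie apart from the other 9.

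The comparison of LPS + PPLG-2V-SA with LPS asked the same of PPLG-2V-SA. Cholesterol synthesis genes were higher, and negative regulators and classical activation effectors lower. Il6 fell from 17.6 ± 4.55 to 8.26 ± 1.87 CPM (log2 fold change -1.09 ± 0.22, adjusted p = 4.24e-04). Tnf fell from 839 ± 138 to 493 ± 36.0 CPM (log2 fold change -0.77 ± 0.11, adjusted p = 1.74e-05). Siglece rose from 2.45 ± 1.09 to 34.1 ± 1.85 CPM (log2 fold change 3.79 ± 0.23, adjusted p = 2.66e-10). In total 4152 genes were higher and 4070 lower. On FPKM plus 1 the split was 5178 and 3082, with a median moved by 0.10.

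Of the cholesterol biosynthesis genes, 22 of 23 rose, 0 fell and 1 were not called (median 2.16; adjusted p = 7.79e-26), with Hmgcs1 at 2.42 ± 0.11 and Lss at 2.22 ± 0.09. Of the negative regulators, 4 of 26 rose, 20 fell and 2 were not called (median -1.36; adjusted p = 1.35e-16), with Socs3 at -3.77 ± 0.11, Il1rn at -4.53 ± 0.13, Nfkbia at -1.87 ± 0.11 and Il10 at -4.76 ± 0.21. Of the classical activation effectors, 5 of 30 rose, 19 fell and 6 were not called (6 and 19 adjusted over the list alone; median -1.79; adjusted p = 1.15e-08), with Saa3 at -6.94 ± 0.19, Lcn2 at -5.13 ± 0.14, Nos2 at -2.67 ± 0.15, Ptgs2 at -4.11 ± 0.26 and the oxidase subunit gene Ncf1 at 2.74 ± 0.13. Of the inflammatory cytokines, 3 of 21 rose, 12 fell and 6 were not called (median -0.73; adjusted p = 2.49e-04, adjusted p = 0.170 with an estimated correlation), with Il33 at -7.39 ± 0.23, Csf3 at -5.01 ± 0.18, Lif at -3.15 ± 0.21 and Il1b at 0.69 ± 0.21. Of the chemokines, 1 of 13 rose, 10 fell and 2 were not called (median -1.54; adjusted p = 8.82e-07, adjusted p = 0.0607 with an estimated correlation), with Cxcl2 at -4.40 ± 0.14, Ccl4 at -3.16 ± 0.12 and Ccl5 at -0.52 ± 0.14, a fall not found on FPKM plus 1 (0.0015) or with length trends removed (-0.04). Of the interferon-stimulated genes, 23 of 44 rose, 7 fell and 14 were not called (median 0.41; adjusted p = 0.00464, adjusted p = 0.225 with an estimated correlation), with Ifi44l at 2.88 ± 0.12, Oas3 at 1.34 ± 0.08, Rsad2 at -1.90 ± 0.10 and Isg15 at -1.19 ± 0.21. Camera called 16 lists, 5 of them with an estimated correlation too.

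Of the G2 and M phase genes, 30 of 32 rose and 0 fell (adjusted p = 6.89e-11, adjusted p = 0.133 with an estimated correlation), with Ccnb2 at 2.45 ± 0.20, and of the S phase genes, 23 of 32 rose and 2 fell (adjusted p = 5.61e-05, adjusted p = 0.353 with an estimated correlation), with Tk1 at 2.50 ± 0.14. Histones had 0 of 20 rose, 11 fell and 9 were not called (0 and 10 adjusted over the list alone; median -2.52, or -2.23 with genes at 0 at their bound; adjusted p = 0.00780, adjusted p = 0.235 with an estimated correlation), with H1f2 at -5.07 ± 0.25. Lysosome and phagocytosis genes had 4 of 36 rose and 23 fell (adjusted p = 0.00132, adjusted p = 0.389 with an estimated correlation), with Ctsl at -2.87 ± 0.19 and the receptor tyrosine kinase gene Axl at 4.43 ± 0.15. In the Siglec and phosphatase list, with 3 of 10 rose and 3 fell (adjusted p = 0.200), Cd33 rose by 2.74 ± 0.17 and Ptpn6 by 1.02 ± 0.12, while Siglec1 changed by -0.80 ± 0.13; the median of the list was -0.09 and its mean 0.45. In the panel of 22 genes 4 rose, 12 fell and 6 were not called, with Cd14 at -0.85 ± 0.12 and Arg1 at least 6.74-fold lower.

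The largest rises were those of Baiap2l1 at 9.77 ± 0.21, the olfactory receptor gene Or5v1b, at least 98.9-fold higher, Atrnl1, 916-fold (counting interval 164 to 36226), Runx3, 703-fold (counting interval 126 to 27787), the laminin gene Lama4 at 7.80 ± 0.41, Tnik at 6.88 ± 0.46, the desaturase gene Scd1 at 6.61 ± 0.28 and Xk at 6.14 ± 0.38. The largest falls were those of S100a8, at least 3674-fold lower, Spry2, at least 279-fold, U90926, at least 222-fold, Morc4, at least 223-fold, Stfa3, 1454-fold (counting interval 497 to 7056), Nrp1, at least 134-fold, Ctag2l1, at least 121-fold, and Plcxd2, at least 115-fold. Neutrophil and mast cell markers had 0 of 3 rose and 3 fell (adjusted p = 7.51e-06). MHC class I genes had 4 that rose and 7 that fell, but 10 and 5 on FPKM plus 1.

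The comparison of LPS + PPLG-4V-SA with LPS asked the same of PPLG-4V-SA. Interferon-stimulated and cholesterol synthesis genes were higher, and negative regulators lower. Il1b rose from 17.6 ± 0.981 to 151 ± 19.5 CPM (log2 fold change 3.10 ± 0.21, adjusted p = 2.51e-09). Il6 rose from 17.6 ± 4.55 to 61.3 ± 5.35 CPM (log2 fold change 1.80 ± 0.21, adjusted p = 1.87e-06). Ccl5 rose from 37.2 ± 7.24 to 178 ± 6.75 CPM (log2 fold change 2.26 ± 0.14, adjusted p = 8.96e-10). Tnf fell from 839 ± 138 to 389 ± 22.5 CPM (log2 fold change -1.11 ± 0.12, adjusted p = 3.89e-07). In total 3775 genes were higher and 3651 lower. On FPKM plus 1 the split was 4810 and 2723, with a median moved by 0.10.

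Interferon-stimulated genes had 33 of 44 rose, 4 fell and 7 were not called (median 0.84; adjusted p = 2.09e-09), with Gbp5 at 3.09 ± 0.21, Gbp3 at 2.57 ± 0.15, Oas3 at 1.38 ± 0.08 and Ifit1 at 0.73 ± 0.19. Cholesterol biosynthesis genes had 21 of 23 rose, 1 fell and 1 were not called (median 1.46; adjusted p = 5.29e-16), with Insig1 at 3.11 ± 0.17 and Lss at 1.47 ± 0.09. Of the negative regulators, 4 of 26 rose, 18 fell and 4 were not called (4 and 19 adjusted over the list alone; median -1.10; adjusted p = 1.71e-10), with Socs3 at -2.99 ± 0.10, Irak3, an inhibitory kinase homologue of TLR signalling, at -2.40 ± 0.14, Nfkbia at -1.73 ± 0.11 and Il10 at -1.92 ± 0.18. Of the classical activation effectors, 7 of 30 rose, 17 fell and 6 were not called (7 and 18 adjusted over the list alone; median -1.17; adjusted p = 5.61e-04, adjusted p = 0.0737 with an estimated correlation), with Hdc at 5.76 ± 0.22, Saa3 at -3.51 ± 0.15, Nos2 at -1.93 ± 0.15 and Ptgs2 at -3.09 ± 0.25. Of the chemokines, 3 of 13 rose and 7 fell (adjusted p = 0.0465, adjusted p = 0.387 with an estimated correlation), with Ccl22 at 4.91 ± 0.23, Cxcl2 at -3.90 ± 0.14 and Ccl2 at 0.99 ± 0.13. Inflammatory cytokines had 7 of 21 rose and 9 fell (adjusted p = 0.392), with Csf3 at -3.31 ± 0.17. G2 and M phase genes had 26 of 32 rose and 0 fell (28 and 0 adjusted over the list alone; adjusted p = 8.91e-11, adjusted p = 0.117 with an estimated correlation), with Kif2c at 1.63 ± 0.11, and S phase genes 21 of 32 rose and 1 fell (adjusted p = 4.73e-05, adjusted p = 0.373 with an estimated correlation), with Rrm2 at 1.20 ± 0.10.

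Histones had 0 of 20 rose, 12 fell and 8 were not called (median -2.46, or -2.29 with genes at 0 at their bound; adjusted p = 0.00291, adjusted p = 0.131 with an estimated correlation), with H1f2 at -3.99 ± 0.23. Camera called 13 lists, 4 of them with an estimated correlation too. Siglec and phosphatase genes had 6 of 10 rose and 3 fell (adjusted p = 0.0843): Siglece rose by 2.81 ± 0.23, Cd33 by 2.53 ± 0.17, Siglec1 by 0.59 ± 0.13 and Ptpn6 by 0.71 ± 0.12. Among the 22 panel genes 10 rose, 9 fell and 3 were not called, with Ifnb1 at 1.98 ± 0.68, not called under 3 alternatives, Cd14 at -0.72 ± 0.12 and Arg1 at least 6.49-fold lower. Neutrophil and mast cell markers had 0 of 3 rose and 3 fell (adjusted p = 7.48e-07), from 201 CPM with LPS, most of it S100a8, to 3.86 on plain totals. TLR4 signalling components had 7 that rose and 9 that fell, and macrophage identity genes 8 and 10, but 10 and 5, and 11 and 8, on FPKM plus 1.

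The largest rises were those of Atrnl1, 806-fold (counting interval 144 to 31857) higher, Baiap2l1 at 9.15 ± 0.21, Runx3, 691-fold (counting interval 124 to 27311), Tnc at 6.30 ± 0.37, Tnik at 6.11 ± 0.47, Trpm6, 76.2-fold (counting interval 25.8 to 372), Tnfsf15 at 5.86 ± 0.61 and Serpinb6b at 5.82 ± 0.26. The largest falls were those of S100a8, 3536-fold (counting interval 1209.6 to 17150.3) lower, Grhl2, at least 371-fold, Tex101, at least 274-fold, Spry2, at least 269-fold, Magohb, at least 244-fold, Steap4, at least 178-fold, Nrp1, at least 129-fold, and Ctag2l1, at least 116-fold.

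**Figure D4:**
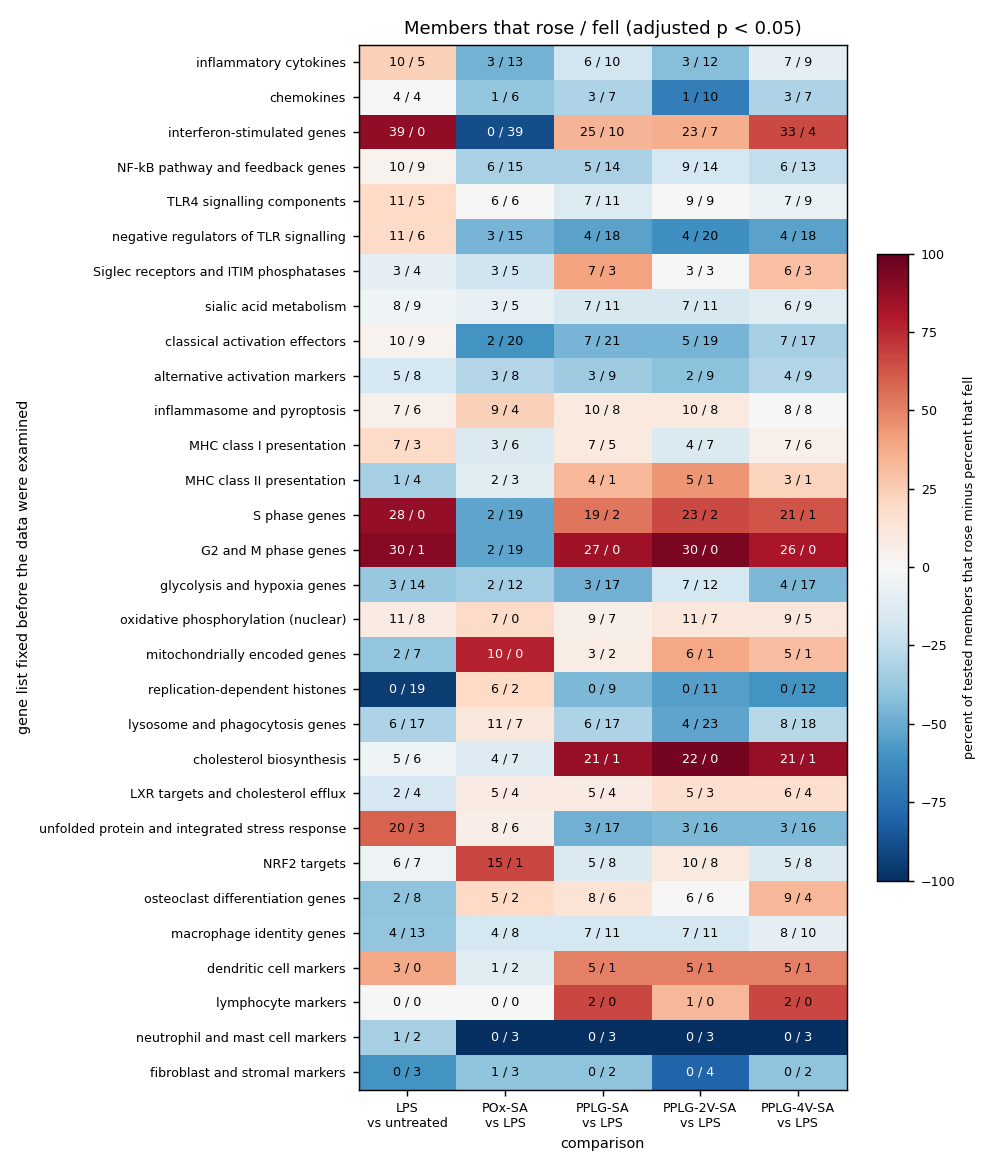
Cells give how many tested members of each list rose and fell in LPS against untreated and in each polymer against LPS, and colour gives the percent that rose minus the percent that fell. Interferon-stimulated genes rose with LPS and fell with POx-SA, and cholesterol genes rose with the 3 PPLG polymers. The balance of some lists, such as NRF2 targets in the first column, turns on FPKM values.

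Of the 7982 genes that LPS changed, each polymer moved some in the opposite direction. POx-SA moved back 3198, PPLG-SA 2956, PPLG-2V-SA 2272 and PPLG-4V-SA 2346, and they moved 975, 2070, 2730 and 2212 further. With only the 2 groups in the fit, unpaired, POx-SA moved back 1635 and PPLG-SA 2551, and with a 2-fold call 784 and 826, so the order of these polymers turns. Independent lists of these sizes would share 999 and 851 genes (higher then lower, and lower then higher) for POx-SA, and 1272 and 1120 for PPLG-SA. They would share 1253 and 1180 for PPLG-2V-SA, above the 1210 and 1062 seen, and 1124 and 1073 for PPLG-4V-SA, against 1222 and 1124. Both comparisons use the 3 LPS libraries, not split into separate controls, so part of any excess may come from sharing them. The covariance of both log2 fold changes was -0.430, -0.226, 0.0659 and -0.0335 for the 4 polymers. In 20 simulations of unchanged groups it averaged 0.00869, but shared LPS noise would make it negative, so they cannot gauge that noise. Of the genes moved back, 1636, 1528, 1050 and 1176 did not differ from untreated by the test, and 469, 604, 612 and 468 passed to the other side of it.

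**Figure D5:**
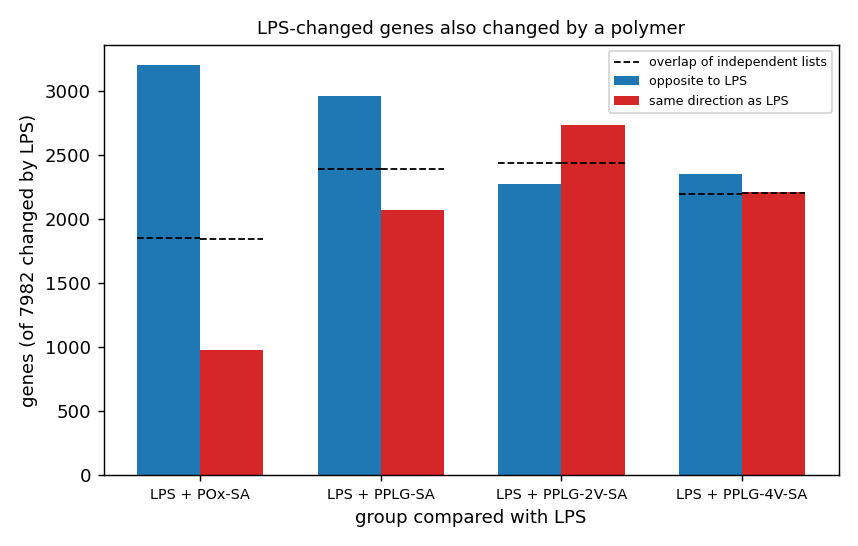
Bars count, for each polymer against LPS, LPS-changed genes called in the opposite and in the same direction as the LPS effect, and dashed lines mark the overlap of independent lists of the same sizes. The opposite direction exceeds that overlap for POx-SA, PPLG-SA and, by less, PPLG-4V-SA, and the same direction exceeds it for PPLG-2V-SA and barely for PPLG-4V-SA.

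PPLG-SA and POx-SA share the ending SA in their labels and differ in the first part. Interferon-stimulated genes and mitotic genes were higher with PPLG-SA than with POx-SA, and NRF2 targets were lower. Il6 differed from 6.61 ± 2.78 to 46.3 ± 0.406 CPM (log2 fold change 2.81 ± 0.23, adjusted p = 2.14e-08), Ccl2 from 31.9 ± 6.22 to 326 ± 19.8 CPM (log2 fold change 3.35 ± 0.14, adjusted p = 5.87e-12), and Siglece from 1.41 ± 0.447 to 11.8 ± 1.49 CPM (log2 fold change 3.05 ± 0.25, adjusted p = 2.08e-08), POx-SA being given first. Tnf was lower with PPLG-SA, at -1.44 ± 0.12. In total 3810 genes were higher and 3972 lower, and on FPKM plus 1 these were 4992 and 2745, with a median moved by 0.13.

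Of the interferon-stimulated genes, 42 of 44 rose, 1 fell and 1 were not called (43 and 1 adjusted over the list alone; median 1.98; adjusted p = 3.45e-37), with Oas2 at 2.58 ± 0.11 and Oasl2 at 4.84 ± 0.20. Of the G2 and M phase genes, 29 of 32 rose, 0 fell and 3 were not called (30 and 0 adjusted over the list alone; median 1.53; adjusted p = 5.41e-23), with Ccna2 at 2.99 ± 0.15, and of the S phase genes, 25 of 32 rose and 3 fell (adjusted p = 4.28e-08, adjusted p = 0.331 with an estimated correlation), with Uhrf1 at 2.11 ± 0.13. Of the cholesterol biosynthesis genes, 22 of 23 rose, 0 fell and 1 were not called (median 1.60; adjusted p = 2.42e-16), with Idi1 at 2.77 ± 0.17. Of the NRF2 targets, 0 of 21 rose, 19 fell and 2 were not called (median -1.09; adjusted p = 8.94e-10), with Hmox1 at -3.13 ± 0.21 and Cat, which encodes catalase, at -1.90 ± 0.10. Of the inflammatory cytokines, 11 of 21 rose and 6 fell (adjusted p = 0.0259, adjusted p = 0.430 with an estimated correlation), with Csf1 at 3.67 ± 0.21 and Osm at -2.04 ± 0.11. Camera called 12 lists, 4 of them with an estimated correlation too. Siglec and phosphatase genes had 5 of 10 rose and 3 fell (adjusted p = 0.206). Siglec1 was higher by 2.35 ± 0.14 and Ptpn6 by 0.64 ± 0.12, and Cd33 did not differ (-0.07 ± 0.16, 95% interval -0.40 to 0.26). Of the 22 panel genes 10 were higher with PPLG-SA, 6 lower and 6 not called. Il1b stood at 3.53 ± 0.22, Il10 at 3.41 ± 0.23, Ccl5 at 2.93 ± 0.15, Cxcl10 at 2.01 ± 0.23, Nos2 at -1.04 ± 0.14, Ptgs2 at -1.16 ± 0.23, Socs3 at -1.02 ± 0.10 and Cd14 at -1.36 ± 0.13.

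The most raised in PPLG-SA were Baiap2l1 at 10.74 ± 0.24, the transcription factor gene Maf, 857-fold (counting interval 153 to 33879.7) higher, Lipg, 735-fold (counting interval 203 to 6073), Atrnl1, 255-fold (counting interval 86.9 to 1237), and Tnc, 205-fold (counting interval 69.9 to 997). Most lowered were Rasgrf2, at least 273-fold, S100a8, 2454-fold (counting interval 440.0 to 96969), Tex101, at least 213-fold, Spry2, at least 141-fold, and Nrp1, at least 139-fold.

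PPLG-2V-SA and PPLG-SA differ by the letters 2V, whose meaning the labels do not give. Classical activation effectors were lower with PPLG-2V-SA. Il6 differed from 46.3 ± 0.406 to 8.26 ± 1.87 CPM (log2 fold change -2.49 ± 0.22, adjusted p = 5.03e-07), Ccl5 from 167 ± 7.08 to 25.9 ± 4.22 CPM (log2 fold change -2.69 ± 0.15, adjusted p = 9.38e-10) and Il1b from 143 ± 7.70 to 28.4 ± 4.54 CPM (log2 fold change -2.33 ± 0.21, adjusted p = 4.35e-07), PPLG-SA being given first. Siglece was higher with PPLG-2V-SA by 1.53 ± 0.20, and Tnf by 0.70 ± 0.11. In total 1980 genes were higher and 1786 lower, and 3065 and 3294 with only these 6 libraries in the fit. On FPKM plus 1 they were 2743 and 1309.

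Of the inflammatory cytokines, 4 of 21 rose, 10 fell and 7 were not called (4 and 11 adjusted over the list alone; median -1.01; adjusted p = 4.44e-08, adjusted p = 0.0605 with an estimated correlation), with Il1a at -2.28 ± 0.19. Of the chemokines, 0 of 13 rose, 9 fell and 4 were not called (median -0.82; adjusted p = 2.15e-08, adjusted p = 0.0605 with an estimated correlation), with Ccl7 at -1.57 ± 0.22 and Ccl2 at -0.54 ± 0.13. Of the classical activation effectors, 5 of 30 rose, 16 fell and 9 were not called (7 and 16 adjusted over the list alone; median -0.49; adjusted p = 1.59e-08), with Saa3 at -3.32 ± 0.19 and Lcn2 at -2.18 ± 0.13. Cholesterol biosynthesis genes had 17 of 23 rose, 0 fell and 6 were not called (20 and 0 adjusted over the list alone; median 0.56; adjusted p = 5.94e-10, adjusted p = 0.0877 with an estimated correlation), with Sqle at 0.93 ± 0.10. Of the lysosome and phagocytosis genes, 1 of 36 rose and 20 fell (1 and 22 adjusted over the list alone; adjusted p = 8.35e-09, adjusted p = 0.196 with an estimated correlation), with the scavenger receptor gene Cd36 at -2.23 ± 0.11. Negative regulators had 5 of 26 rose and 10 fell (6 and 12 adjusted over the list alone; adjusted p = 4.02e-07, adjusted p = 0.0593 with an estimated correlation), with Dusp1 at -2.44 ± 0.15. Camera called 11 lists, and classical activation effectors alone with an estimated correlation too. Interferon-stimulated genes had 11 of 44 rose and 15 fell (12 and 16 adjusted over the list alone; adjusted p = 0.323), against 12 and 10 on FPKM plus 0.1. Of the Siglec and phosphatase genes, 2 of 10 rose and 3 fell (adjusted p = 0.887), with Siglec1 at -1.42 ± 0.13 and Ptpn6 at 0.69 ± 0.12. Its median was 0.04, its mean 0.02 and its camera direction down. In the panel of 22 genes 6 were higher, 8 lower and 8 not called, with Il10 at -2.21 ± 0.20, Nos2 at -0.46 ± 0.14, a call lost under 3 alternatives, and Ptgs2 at -1.10 ± 0.23.

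Most raised were Gpr84, a receptor for medium-chain fatty acids, at 3.67 ± 0.29, the mitochondrial gene ND4L at 3.19 ± 1.03, not called under 9 alternatives, Exosc6 at 3.19 ± 0.46, Hspa1b at 2.91 ± 0.43 and Csf2 at 2.66 ± 0.26. The most lowered were Il33 at -6.08 ± 0.23, Slamf7 at -4.11 ± 0.26, Urah at -3.93 ± 0.23, the complement gene Cfb at -3.88 ± 0.25 and Timp1 at -3.50 ± 0.24.

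PPLG-4V-SA and PPLG-SA gave the closest groups of these comparisons. Socs3 was higher with PPLG-4V-SA, and interferon-stimulated genes shifted up as a list. Socs3 differed from 171 ± 9.46 to 355 ± 25.2 CPM (log2 fold change 1.05 ± 0.10, adjusted p = 5.12e-05) and Ccl2 from 326 ± 19.8 to 519 ± 43.5 CPM (log2 fold change 0.67 ± 0.13, adjusted p = 0.0147), PPLG-SA being given first. Cd14 was higher by 0.59 ± 0.12, and the calls of Ccl2 and Cd14 were each lost under 5 alternatives. In total 145 genes were higher and 78 lower. With only these 6 libraries in the fit there were 1579 and 1790, and without PPLG-SA replicate 1 there were 4 and 1, so these counts depend on how the spread is estimated.

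For the other 19 panel genes no difference was called, which does not show that both polymers act alike. The 95% interval of the log2 difference was 0.12 to 0.61 for Tnf, -0.02 to 0.83 for Il6, -0.32 to 0.49 for Il1b, -0.19 to 0.38 for Ccl5 and 0.25 to 1.02 for Il10. It was -0.02 to 0.58 for Nos2, 0.13 to 0.96 for Siglece, -0.46 to 0.19 for Cd33, -0.31 to 0.24 for Siglec1 and 0.11 to 0.63 for Ptpn6. Interferon-stimulated genes had 5 of 44 rose, 0 fell and 39 were not called (16 and 0 adjusted over the list alone; median 0.31; adjusted p = 5.89e-10). Of the S phase genes, 2 of 32 rose and 0 fell (adjusted p = 0.00679, adjusted p = 0.758 with an estimated correlation), of the mitochondrially encoded genes, 4 of 13 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 3.65e-04, adjusted p = 0.429 with an estimated correlation), with ND1 at 0.92 ± 0.17, and of the macrophage identity genes, 2 of 23 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.0199, adjusted p = 0.420 with an estimated correlation), with Cebpa at 1.05 ± 0.19, calls lost under 4 and 5 alternatives. Camera called 6 lists, and interferon-stimulated genes alone with an estimated correlation too. Cholesterol biosynthesis genes had 0 of 23 rose and 0 fell (adjusted p = 0.192), inflammatory cytokines 0 of 21 rose and 0 fell (adjusted p = 0.0859) and Siglec and phosphatase genes 0 of 10 rose and 0 fell (2 and 1 adjusted over the list alone; adjusted p = 0.933), with a median of -0.03 and a mean of 0.01.

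The most raised were Gpr84 at 1.68 ± 0.29, Ppp1r10 at 1.41 ± 0.33, the endosomal receptor gene Tlr13 at 1.34 ± 0.26, Tbcc at 1.27 ± 0.28 and Sema4c at 1.25 ± 0.19, calls lost under 4, 8, 5, 6 and 1 alternatives. Among the most lowered were Slc18a1 at -2.63 ± 0.49, Rabepk at -1.06 ± 0.19, Lrrc69 at -0.88 ± 0.19 and Zfp326 at -0.87 ± 0.15, calls lost under 5, 3, 7 and 3.

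PPLG-4V-SA and PPLG-2V-SA differ in their labels by 4V and 2V. Cytokines, chemokines and negative regulators were higher with PPLG-4V-SA, and cholesterol synthesis genes were lower. Il6 differed from 8.26 ± 1.87 to 61.3 ± 5.35 CPM (log2 fold change 2.89 ± 0.23, adjusted p = 1.31e-07), Ccl5 from 25.9 ± 4.22 to 178 ± 6.75 CPM (log2 fold change 2.78 ± 0.15, adjusted p = 8.02e-10) and Il10 from 5.19 ± 0.463 to 37.4 ± 2.65 CPM (log2 fold change 2.84 ± 0.20, adjusted p = 3.69e-08), PPLG-2V-SA being given first. Siglec1 was higher by 1.39 ± 0.13, and Siglece stood at -0.99 ± 0.19. In total 1015 genes were higher and 602 lower, and 2295 and 2122 with only these 6 libraries in the fit, but down to 635 and 268 with 1 library left out.

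Of the chemokines, 10 of 13 rose, 0 fell and 3 were not called (median 1.06; adjusted p = 1.13e-18), with Ccl7 at 2.31 ± 0.21 and Ccl2 at 1.21 ± 0.13. Of the inflammatory cytokines, 10 of 21 rose, 1 fell and 10 were not called (15 and 3 adjusted over the list alone; median 1.10; adjusted p = 2.94e-17), with Il1a at 2.50 ± 0.19 and Il1b at 2.41 ± 0.21. Of the classical activation effectors, 17 of 30 rose, 3 fell and 10 were not called (18 and 4 adjusted over the list alone; median 0.79; adjusted p = 8.59e-18), with Lcn2 at 2.57 ± 0.13 and Hdc at 2.43 ± 0.17. Of the negative regulators, 12 of 26 rose, 0 fell and 14 were not called (15 and 2 adjusted over the list alone; median 0.46; adjusted p = 3.55e-16), with Il1rn at 3.44 ± 0.13 and Socs3 at 0.77 ± 0.10. Of the interferon-stimulated genes, 18 of 44 rose, 3 fell and 23 were not called (23 and 6 adjusted over the list alone; median 0.39; adjusted p = 7.81e-09), with Rsad2 at 1.58 ± 0.09 and Isg15 at 0.78 ± 0.21, the latter not called under 4 alternatives. Of the cholesterol biosynthesis genes, 0 of 23 rose, 18 fell and 5 were not called (0 and 22 adjusted over the list alone; median -0.68; adjusted p = 1.67e-20), with Hmgcs1 at -0.92 ± 0.10. Camera called 15 lists, 11 of them with an estimated correlation too. Among the 22 panel genes 11 were higher, 1 lower and 10 not called. Tnf was among the latter, with a 95% interval of -0.58 to -0.10.

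Most raised were Il33 at 5.99 ± 0.23, Urah at 4.31 ± 0.23, Slamf7 at 4.15 ± 0.26, Cfb at 3.85 ± 0.25 and Pdpn at 3.64 ± 0.20. The most lowered were Hspa1b at -4.57 ± 0.50, the metallothionein genes Mt1 at -2.41 ± 0.29 and Mt2 at -2.11 ± 0.22, Gpr84 at -2.00 ± 0.25 and Lama4 at -1.98 ± 0.24.

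Each polymer group was also set against untreated cells. With LPS + POx-SA, Tnf stayed above the untreated level, at 1.35 ± 0.12, while Il6 (0.16 ± 0.27), Ccl5 (-0.14 ± 0.15) and Cxcl10 (0.24 ± 0.27) did not differ by the test. Nos2 stood at -2.15 ± 0.15, Ccl2 at -2.79 ± 0.14 and Il10 at -2.53 ± 0.25. In total 4093 genes were higher and 3767 lower, and on FPKM plus 1 these were 5242 and 2767, with a median moved by 0.13. Of the NRF2 targets, 15 of 21 rose, 0 fell and 6 were not called (15 and 1 adjusted over the list alone; median 0.97; adjusted p = 5.15e-06), with Taldo1 at 1.56 ± 0.16, and of the stress response genes, 20 of 29 rose and 1 fell (adjusted p = 1.52e-06, adjusted p = 0.210 with an estimated correlation), with Trib3 at 2.98 ± 0.18. Interferon-stimulated genes had 13 of 44 rose and 16 fell (adjusted p = 0.585), against 13 and 11 on FPKM plus 1. The most raised were Hspa1a, at least 100.2-fold, Slc40a1 at 5.23 ± 0.30, the DNA-sensing receptor gene Tlr9 at 4.15 ± 0.49, Zfp418 at 4.14 ± 0.58 and Acot2 at 3.79 ± 0.37. Most lowered were Ovgp1, at least 165-fold, Ugt1a8, at least 92.5-fold, Csn1s1 at -6.89 ± 0.48, H2ac6 at -5.57 ± 0.58 and S100a8 at -5.56 ± 0.28.

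With LPS + PPLG-SA, Tnf was not called against untreated cells (-0.10 ± 0.11, 95% interval -0.34 to 0.15), but on FPKM plus 1 it was called higher, at 0.38, while Il6 stood at 2.97 ± 0.25, Il1b at 2.87 ± 0.22 and Ccl5 at 2.79 ± 0.15. Socs3 stood at -2.78 ± 0.10, Nos2 at -3.20 ± 0.15 and Siglece at 2.27 ± 0.25. In total 4730 genes were higher and 4425 lower, and on FPKM plus 1 these were 6730 and 2872, with a median moved by 0.26. Interferon-stimulated genes had 41 of 44 rose, 0 fell and 3 were not called (42 and 0 adjusted over the list alone; median 1.76; adjusted p = 1.40e-19), with Gbp3 at 5.21 ± 0.21. G2 and M phase genes had 31 of 32 rose and 0 fell (adjusted p = 1.71e-29). Most raised were Atrnl1, at least 159-fold, Baiap2l1 at 8.82 ± 0.21, Lipg at 7.76 ± 0.34, Runx3, 171-fold (counting interval 47.1 to 1415), and Serpinb6b at 6.97 ± 0.30. The most lowered were S100a8, 115168-fold (counting interval 20669.7 to 4548970.0), U90926, at least 644-fold, Tex101, at least 245-fold, Rasgrf2, at least 178-fold, and S100a9, at least 141-fold.

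With LPS + PPLG-2V-SA, Tnf stood at 0.61 ± 0.11 against untreated cells, Siglece at 3.80 ± 0.25 and Ptpn6 at 2.08 ± 0.13, while Il6 (0.48 ± 0.26) and Ccl5 (0.10 ± 0.15) did not differ by the test, though both did on FPKM plus 1. Nos2 stood at -3.66 ± 0.16 and Ptgs2 at -3.43 ± 0.25. In total 5154 genes were higher and 4825 lower, and on FPKM plus 1 these were 7185 and 3008, with a median moved by 0.34. Cholesterol biosynthesis genes had 23 of 23 rose, 0 fell and 0 were not called (median 2.24; adjusted p = 1.14e-14). Of the interferon-stimulated genes, 43 of 44 rose, 0 fell and 1 were not called (median 1.83, or 1.77 with genes at 0 at their bound; adjusted p = 5.88e-14), and of the negative regulators, 5 of 26 rose and 18 fell (adjusted p = 1.34e-07). Most raised were ND4L, at least 387-fold (uncertain), Atrnl1, at least 170-fold, Or5v1b, at least 55.0-fold, Baiap2l1 at 9.35 ± 0.22 and Lama4, 273-fold (counting interval 75.5 to 2258). Most lowered were S100a8, at least 48132-fold, Stfa3, 6317-fold (counting interval 2161 to 30638), U90926, at least 808-fold, Csta3, at least 437-fold, and Stfa2, at least 411-fold.

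With LPS + PPLG-4V-SA, Tnf stood at 0.27 ± 0.11 against untreated cells, a call that 10 alternatives did not make, Il6 at 3.37 ± 0.25, Il1b at 2.95 ± 0.22, Ccl5 at 2.88 ± 0.15 and Ccl2 at 1.24 ± 0.13. Nos2 stood at -2.92 ± 0.15 and Socs3 at -1.73 ± 0.10. In total 4947 genes were higher and 4526 lower, and on FPKM plus 1 these were 7250 and 2680, with a median moved by 0.33. Interferon-stimulated genes had 44 of 44 rose, 0 fell and 0 were not called (median 2.05; adjusted p = 2.92e-24). Most raised were ND4L, at least 162-fold (uncertain), Atrnl1, at least 149-fold, Baiap2l1 at 8.72 ± 0.21, Lipg at 8.15 ± 0.34 and Runx3, 192-fold (counting interval 53.0 to 1587). The most lowered were S100a8, 46327-fold (counting interval 15852 to 224650.0), Tex101, at least 296-fold, Ovgp1, at least 225-fold, S100a9, at least 171-fold, and H2ac6, at least 158-fold.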

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

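Of the tests in this part, those of another cell population, of a response to the PPLG polymers, of library size in the pair of replicates 3, of shared reads, of swapped labels and of cycling cells were chosen after the results were seen.

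Some genes and lists moved in opposite directions from LPS under a pair of polymers, and the difference itself was tested by edgeR, or by camera for lists. Between PPLG-SA and POx-SA, Il6 differed by 2.81 ± 0.23 (adjusted p = 2.14e-08), from a rise of 1.40 with PPLG-SA and a change of -1.41 with POx-SA. Ccl2 differed by 3.35 ± 0.14 (0.32 and -3.03), Ccl5 by 2.93 ± 0.15 (2.17 and -0.76), Siglece by 3.05 ± 0.25 (2.26 and -0.79), Siglec1 by 2.35 ± 0.14 (0.63 and -1.73) and Ptpn6 by 0.64 ± 0.12 (0.34 and -0.31). The median log2 difference was 1.98 for interferon-stimulated genes, 1.04 for S phase genes and 1.53 for G2 and M phase genes. With an estimated correlation the S phase difference was not called (adjusted p = 0.331), nor were the shifts from LPS with POx-SA and PPLG-SA of S phase genes (adjusted p = 0.594 and 0.546) and G2 and M phase genes (0.272 and 0.155), nor the interferon-stimulated genes with PPLG-SA (0.149). Between PPLG-2V-SA and PPLG-SA, Il6 differed by -2.49 ± 0.22, Ccl5 by -2.69 ± 0.15 and Siglec1 by -1.42 ± 0.13. Between PPLG-4V-SA and PPLG-2V-SA, Il6 differed by 2.89 ± 0.23, Ccl5 by 2.78 ± 0.15 and Siglec1 by 1.39 ± 0.13. The fall of Ccl5 with PPLG-2V-SA was not found on FPKM plus 1 (0.0015), and the calls of Siglece and Ptpn6 with POx-SA were lost under 7 and 8 alternatives, and those of Ccl2 and Ptpn6 with PPLG-SA under 6 and 4. The CPM of both groups overlapped for Siglece and Ptpn6 in POx-SA against LPS and for Ccl2 in PPLG-SA against LPS.

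The 9 libraries of the PPLG groups differed from the other 9 by at least 8-fold, at 1 CPM or more, in 63 genes, and none of the 9 other ways to part the 6 groups 3 against 3 gave such a gene. Gene-length bias as the whole cause is argued against, since 95.2% of these genes kept the gap with length trends removed. A culture of RAW264.7 from another population or stock is a candidate explanation: 6 Y-linked genes had a median absolute log2 fold change of 1.89 between PPLG-SA and LPS, at percentile 99.97 of 10000 random sets of like expression, and 5 moved the same way. A response to the PPLG polymers cannot be told apart from this, because 0 libraries with a PPLG polymer had a summed Y-linked CPM within the range of the libraries without one, nor can gain or loss of chromosome segments, since 3.39% of the 59 genes with a position had another as nearest tested gene, with a 95% upper bound (10.3%) above percentile 99 of random sets (5.08%), and genes of chromosome 9 had medians of -0.25, -0.22 and -0.22 with the PPLG polymers and -0.01 with POx-SA. If another culture is the cause, differences between any PPLG group and LPS, POx-SA or untreated cells may mix the polymer with the culture.

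Replicates 3 of LPS and of LPS + POx-SA deviated from their group means together, with a correlation of 0.904 across 10055 genes and 0.739 over all tested genes. With length trends removed it was 0.861, which argues against gene-length bias as the whole cause. Thinning to the lowest total (0.884) keeps composition and cannot test library size. Of 69 genes moved at least 4-fold the same way in both libraries, 59.4% carried a predicted, clone or copy name, against 24.6% at percentile 99 of random sets. This is consistent with reads shared between gene copies or overlapping genes having been counted another way in these 2 libraries, as a hypothesis. Gm42427 stood at 0 and 0.353 CPM in them and at 1008 to 2752 CPM in the other 16, and ND3 at 37.7 and 78.2 against 0 to 4.71 CPM, and no biological explanation was tested.

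Nos2 and the replication-dependent histones were higher in untreated cells than after LPS, as were the shares of counts of Malat1 (0.458% and 0.0755%), Neat1 (1.22% and 0.572%) and mitochondrially encoded genes (4.54% and 3.07%). Swapped labels of LPS and untreated are argued against by the 39 interferon-stimulated genes that were higher in the libraries labelled LPS. A change in the share of cycling cells as the whole cause is argued against by 19 histones that were lower while 28 of 32 S phase genes rose. With every library thinned to 9755591 counts, 17 of these 20 genes were still called lower, Nos2 at -1.01. Thinning keeps composition, so it cannot test unequal depth as a cause. What sets these transcripts apart stays open, and an effect of LPS at the unstated time of harvest is among the explanations left untested.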

How the results depend on the processing

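The alternatives named above as added were chosen after the data were seen. Counts of called genes, lists and genes moved back gave 36 results, with 498 values within 1.5 times the reported count and 86 outside. Named genes gave 454 results and 7170 values. Of these 7002 kept direction and side of the threshold, 134 no longer passed, 30 newly passed and 4 reversed. Many genes were picked by fold or p, which favours stability. Leaving out 1 library lost 59.6% to 97.8% of all calls between PPLG-4V-SA and PPLG-SA. It lost 26.3% to 43.7% between either and PPLG-2V-SA, and 5.54% to 14.3% elsewhere. On FPKM plus 1 and plus 0.1, Ccl5 in PPLG-2V-SA against LPS reversed to 0.0015 and 0.0016, and Tnf in PPLG-SA against untreated to 0.38 and 0.38. Whether FPKM lacking TMM factors explains either was not tested. The call of Ugt1a8 in POx-SA against untreated was lost by DESeq2, and other lost calls are given beside the gene. In PPLG-4V-SA against PPLG-SA these were the calls of 13 named genes, and that of Socs3 was lost under none. With 3 libraries per group smaller changes are missed, as simulated 1.5-fold changes show.

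A call that also needs a 2-fold change has fewer genes by construction. It left 1889 higher and 1670 lower in LPS against untreated, 927 and 1217 in POx-SA, 1611 and 1882 in PPLG-SA, 1791 and 1957 in PPLG-2V-SA and 1455 and 1553 in PPLG-4V-SA against LPS. It left 1621 and 1695 in PPLG-SA against POx-SA, 463 and 547 in PPLG-2V-SA against PPLG-SA, 30 and 30 in PPLG-4V-SA against PPLG-SA and 308 and 85 in PPLG-4V-SA against PPLG-2V-SA. Against untreated it left 1738 and 1783 in POx-SA, 2516 and 2545 in PPLG-SA, 3079 and 2991 in PPLG-2V-SA and 2816 and 2590 in PPLG-4V-SA. Genes moved back were then 784, 826, 528 and 517 for the 4 polymers in this order.

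With only the 2 compared groups in the fit, POx-SA against LPS gave 1335 higher and 1726 lower and moved back 1635 genes. PPLG-2V-SA against PPLG-SA gave 3065 and 3294. PPLG-4V-SA gave 1579 and 1790 against PPLG-SA and 2295 and 2122 against PPLG-2V-SA. Here spread is not shared. Sharing may make p too small for POx-SA against LPS, where spread was larger, and too large between PPLG groups. On FPKM plus 1 and plus 0.1 the genes lower were 2304 and 2276 in LPS against untreated, 2872 and 2889 in PPLG-SA, 3008 and 3056 in PPLG-2V-SA and 2680 and 2674 in PPLG-4V-SA against untreated, and the cause was not tested. PPLG-4V-SA against PPLG-SA gave 362 and 283 by DESeq2, 126 lower with no filter, 460 higher on FPKM plus 1, 247 higher on FPKM plus 0.1, and 261 and 247 with length trends removed, and PPLG-4V-SA against PPLG-2V-SA gave 1033 lower with length trends removed. The cause was not tested.

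Leaving out 1 library in turn, PPLG-4V-SA against PPLG-SA gave 4 to 57 higher and 1 to 33 lower, the lowest without PPLG-SA replicate 1, and PPLG-4V-SA against PPLG-2V-SA 635 to 834 and 268 to 415. These lie below the reported 145, 78, 1015 and 602, with fewer libraries in the fit by construction, and the other 32 counts stayed within 1.5 times. With the correlation estimated per list, camera called 2 lists in LPS against untreated, 5, 3, 5 and 4 in POx-SA, PPLG-SA, PPLG-2V-SA and PPLG-4V-SA against LPS, and 17 in the 4 comparisons between polymers. By fry, which does not compare a list with other genes, they were 20, 18, 26, 26, 26 and 67.

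The replicate block in the fit of all libraries changed no call count by over 1.5 times. With only LPS and LPS + POx-SA in the fit, it gave 2601 higher and 2742 lower, against 1335 and 1726 without it.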

Other observations

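No test in this part was chosen after its result was seen. Stress response genes, of which 20 rose after LPS, fell more often than they rose with each PPLG polymer against LPS. Of this list, 3 of 29 rose and 17 fell (adjusted p = 0.00156, adjusted p = 0.378 with an estimated correlation) with PPLG-SA, 3 of 29 rose and 16 fell (3 and 17 adjusted over the list alone; adjusted p = 3.46e-04, adjusted p = 0.313 with an estimated correlation) with PPLG-2V-SA and 3 of 29 rose and 16 fell (adjusted p = 2.79e-05, adjusted p = 0.221 with an estimated correlation) with PPLG-4V-SA. Herpud1 stood at -2.54 ± 0.10, -2.65 ± 0.10 and -2.65 ± 0.10. Alternative activation markers had 3 of 17 rose and 9 fell (adjusted p = 0.0260, adjusted p = 0.119 with an estimated correlation), 2 of 17 rose and 9 fell (2 and 10 adjusted over the list alone; adjusted p = 6.09e-04) and 4 of 17 rose and 9 fell (adjusted p = 0.0257, adjusted p = 0.114 with an estimated correlation), with Tgm2, a transglutaminase, at -3.80 ± 0.34, -4.29 ± 0.34 and -3.77 ± 0.33. Il4ra, a subunit of the interleukin-4 receptor, stood at -1.62 ± 0.11, -1.81 ± 0.11 and -1.42 ± 0.11. The summed Y-linked CPM of these groups differed from that with LPS, as given above.

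The desaturase genes Scd1 and Scd2 rose with each PPLG polymer, Scd1 by 5.51 ± 0.27, 6.61 ± 0.28 and 5.41 ± 0.27 and Scd2 by 3.56 ± 0.17, 4.38 ± 0.17 and 3.60 ± 0.17, while the lipid droplet gene Plin2 stood at -3.87 ± 0.21, -4.98 ± 0.22 and -3.71 ± 0.21. Their list, LXR targets and cholesterol efflux, was not called (adjusted p = 0.214, 0.107 and 0.0572). Ccr7, a chemokine receptor, rose by 3.74 ± 0.44, 3.17 ± 0.44 and 4.65 ± 0.43, and the class II gene H2-Eb1 by 2.65 ± 0.34, 2.45 ± 0.34 and 2.59 ± 0.34. On plain totals, dendritic cell markers summed to 209 CPM with LPS and 462, 365 and 481 CPM with these polymers, and fibroblast markers to 1788 and to 733, 504 and 796 CPM.

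The 6 libraries of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. In edgeR fits of only these libraries the real split, 1 of the 10, called 7334 genes in LPS against untreated, and 3061, 7112, 7338 and 6677 in POx-SA, PPLG-SA, PPLG-2V-SA and PPLG-4V-SA against LPS. It called 5968 in PPLG-SA against POx-SA, 6359 in PPLG-2V-SA against PPLG-SA, 3369 in PPLG-4V-SA against PPLG-SA and 4417 in PPLG-4V-SA against PPLG-2V-SA. Against untreated it called 6416, 10112, 10679 and 10463 in the same order of polymers. The highest other split called 0 genes at an adjusted p below 0.05, and 2 in PPLG-4V-SA against PPLG-SA. Other splits mix groups on each side, so group differences widen their spread and the counts cannot test chance.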
